A study of Mus musculus with 17 samples.

How the data were processed

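RNA was measured in common myeloid progenitors sorted from mouse fetal liver and adult bone marrow, in 17 libraries of 7 groups. Per the labels' protocols, the input was total RNA, and cDNA was made with the SMARTer ultra-low-input chemistry before low-input library preparation. The submitters' processing notes name cutadapt, TopHat2, HTSeq and the mouse build mm10. Versions, parameters, the strand used for counting and the order of the steps are not given in the sources used here. The deposited values are unnormalized counts of reads or read pairs per RefSeq transcript for each library, with 33818 accessions, made by the authors with HTSeq as shown by its closing summary lines. The comparisons had been planned for counts per gene, but the files hold counts per transcript. HTSeq sets aside reads that fit more than 1 transcript. These ambiguous reads were 23.8% to 29.8% of uniquely placed reads, and reads outside any transcript were 8.87% to 19.3%. Both were left out of library sizes and tests.

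Accessions were named from a RefSeq table for GRCm38.p6 (33435) or, where absent there, from GENCODE vM21 (191), and 192 had no name. Counts were summed over the transcripts of a gene, which gave 24416 genes. Of 5108 genes with more than 1 transcript, 1328 (26.0%) had a total of 0. Setting aside reads that fit several transcripts lowers such genes, but how many of the 1328 were at 0 for this reason and how many were not expressed was not tested. Myc, Kit, Cebpa and Irf7, each with more than 1 transcript, had 0 counts and were not analysed here. Genes with 1 transcript can also lose reads, to overlapping genes or near-identical copies: Hba-a1, Hbb-bt and Rpl26, with 1 transcript each, had 0 counts. A fit with only the 19308 genes of 1 transcript was run, which does not remove this loss. Summed counts ranged from 14957111 to 28165554 per library, and the 0.359 CPM of Lin28b in wild-type bone marrow rests on 21 counts over 3 libraries. A count of 0 in the inducible let-7 library allows up to 0.116 CPM (3 counts). All tables were made with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9) and R 4.3.3.

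Groups, comparisons, gene lists, tests, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM library sizes, filterByExpr on the group, 13558 genes) in 1 fit of all 17 libraries with 7 group means and 10 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were wild-type fetal liver against wild-type bone marrow, the libraries labelled Lin28b knockout against wild-type fetal liver, the mean of the LIN28B lines and each line against wild-type bone marrow, vavcre against no vavcre, and the let-7b/c knockout against wild-type bone marrow. The inducible let-7 library has no replicate and got no test. Its list medians were set against 10000 random lists matched on mean level. Log2 CPM used a prior count of 2. Where a group had 1 to 3 counts of a gene the ratio is given with a 95% counting interval. Where it had 0, a bound from a floor of 3 counts over the group is given.

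Fixed gene lists were tested with limma 3.58.1 (camera on voom values, two-sided, preset correlation 0.01, at least 5 tested members), adjusted over 22 lists and 5 comparisons together. They covered the axis, let-7 targets, imprinted and fetal growth genes, erythroid, megakaryocyte, granulocyte, monocyte and dendritic, lymphoid, mast cell, stem and multipotent progenitor, hepatocyte, and stroma and endothelium markers. The others were G1/S, G2/M, interferon response, MHC class I, heme and iron, ribosomal protein, oxidative phosphorylation, immediate early and heat shock, glycolysis and cholesterol synthesis genes. Embryonic globins, with 3 tested members, were described only. Of each list, members were counted as called over all genes and as adjusted over the list alone.

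Genes were named by rule: the axis list in full, the 8 largest rises and 8 largest falls among called genes with no overlap between libraries and at least 10 CPM in the higher group, and up to 3 called members of each list past its test, in the list's direction, by smallest p. For the inducible let-7 library the rule took the 8 highest above and 8 lowest below the wild-type range among genes at 30 CPM or more. Some genes that the rule selects are not reported here. Genes outside the rule are marked in the text, except list members that describe other cell types. Predicted genes, pseudogenes, small RNAs, Xist and Y-linked genes were left out of the rule.

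Developmental position was the projection of log2 CPM on the line from the wild-type bone marrow mean to the wild-type fetal liver mean over all tested genes. A wild-type library was left out of the mean that placed it, and other libraries were placed with each wild-type library of their own tissue left out in turn and averaged. Differences were tested with two-sided exact permutation tests. Shared effects were set against 20 simulations of unchanged groups that use the same controls. Seed matches were searched in annotated 3′ UTRs, and the mean change of genes with the match was ranked among 8-mers of the same base composition held by at least 30 tested genes.

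The edgeR fit was tested on simulated data with 200 changed genes per comparison. It recovered 47% to 69% of 2-fold and 77% to 90% of 4-fold changes and called 3 to 10 unchanged genes. For LIN28B induction only, camera (20 of 20 shifted, 0 of 20 unshifted lists called), the seed test and position were simulated. The larger vavcre spread and correlated lists were not. Alternatives were DESeq2 size factors, no filter, DESeq2 1.42.0, limma-voom with sample quality weights, only the groups compared, title numbers as blocks, the 4 LIN28B libraries as 1 group, each library left out in turn, camera with an estimated correlation, limma's fry test, other prior counts (0.5), the 1000 genes with the largest wild-type difference or genes at 10 CPM or more for position, and a 7-mer seed match. Chosen after seeing the data were fits with only single-transcript genes, without the inducible let-7 library, without that and the vavcre libraries, and with GC and length trends removed. Sex was read from Xist and Ddx3y: the wild-type bone marrow and LIN28B libraries without vavcre were male, the vavcre and let-7b/c knockout libraries female, and the fetal liver groups with 3 libraries mixed. The induced transgene and let-7 itself were not analysed here.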

Results

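The series measured messenger RNA in common myeloid progenitors (CMPs), the precursors of granulocytes, monocytes, red cells and platelets, sorted by flow cytometry from mouse fetal liver and adult bone marrow. Its stated subject is the control of Lin28b and let-7 while myeloid cells develop. LIN28B is an RNA-binding protein of fetal blood progenitors that blocks maturation of let-7 microRNAs, and let-7 represses messages that carry matching sites in their 3′ untranslated regions (UTRs). The 17 libraries fell into 7 groups by their labels: wild-type fetal liver (n = 3), wild-type adult bone marrow (n = 3), Lin28b knockout fetal liver (n = 3), let-7b/c knockout bone marrow (n = 3), inducible LIN28B bone marrow without vavcre (n = 2), inducible LIN28B bone marrow with vavcre (n = 2), and an inducible let-7 fetal liver library (n = 1). The design text describes vavcre as restricting induction to blood-forming cells. The counts on transcripts ranged from 14957111 to 28165554 per library.

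Levels are given in CPM (counts scaled to a common library size), as mean ± SD over the libraries of a group. Folds are fitted ratios of group means, and for LIN28B induction the geometric mean of the folds of its lines with and without vavcre. Adjusted p-values are two-sided and come from edgeR's quasi-likelihood test over 13558 genes unless another test is named. Genes named for the largest rises and falls had no overlap between the libraries of the groups compared. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Reads were amplified without molecular identifiers, so counting intervals and floors cover counting error only. Of 110 tests of fixed gene lists, 55 passed with limma's camera test at a preset correlation, and 11 of these held with an estimated correlation. The 11 were the axis, let-7 target, G1/S, interferon and MHC class I lists in the developmental comparison, the erythroid and the heme and iron lists in the libraries labelled Lin28b knockout, the let-7 target, G1/S and immediate early lists after LIN28B induction, and the monocyte and dendritic list in the let-7b/c knockout.

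The targeted gene was examined in every group before any comparison. Lin28b (NM_001031772, chromosome 10, 45376617 to 45486314 in GRCm38) stood at 104 ± 17.6 CPM in wild-type fetal liver (n = 3) and at 0.359 ± 0.351 CPM in wild-type bone marrow (n = 3). In the libraries labelled Lin28b knockout it stood at 104 ± 12.9 CPM (n = 3), with single libraries from 88.9 to 112 CPM, a log2 difference from wild-type fetal liver of -0.00 (edgeR adjusted p = 1). The counts cover the whole transcript and cannot show the loss of single exons, and these libraries are called "labelled Lin28b knockout" throughout. LIN28B induction gave 2.67 ± 0.858 CPM of Lin28b without vavcre (n = 2) and 2.83 ± 1.55 CPM with vavcre (n = 2), against 91.2 CPM in the inducible let-7 library. The sources used here do not give the sequence of the induced LIN28B, and the counts are those of the mouse Lin28b transcript. In the let-7b/c knockout Lin28b stood at 0.219 ± 0.0999 CPM (n = 3). The let-7 hairpin genes could not check that genotype, since Mirlet7b and Mirlet7c-2 had 0 counts and Mirlet7c-1 had 1 count over all 17 libraries. The labels also give doxycycline induction of LIN28B as the treatment of all 17 libraries, wild-type and knockout alike.

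**Figure D1:**
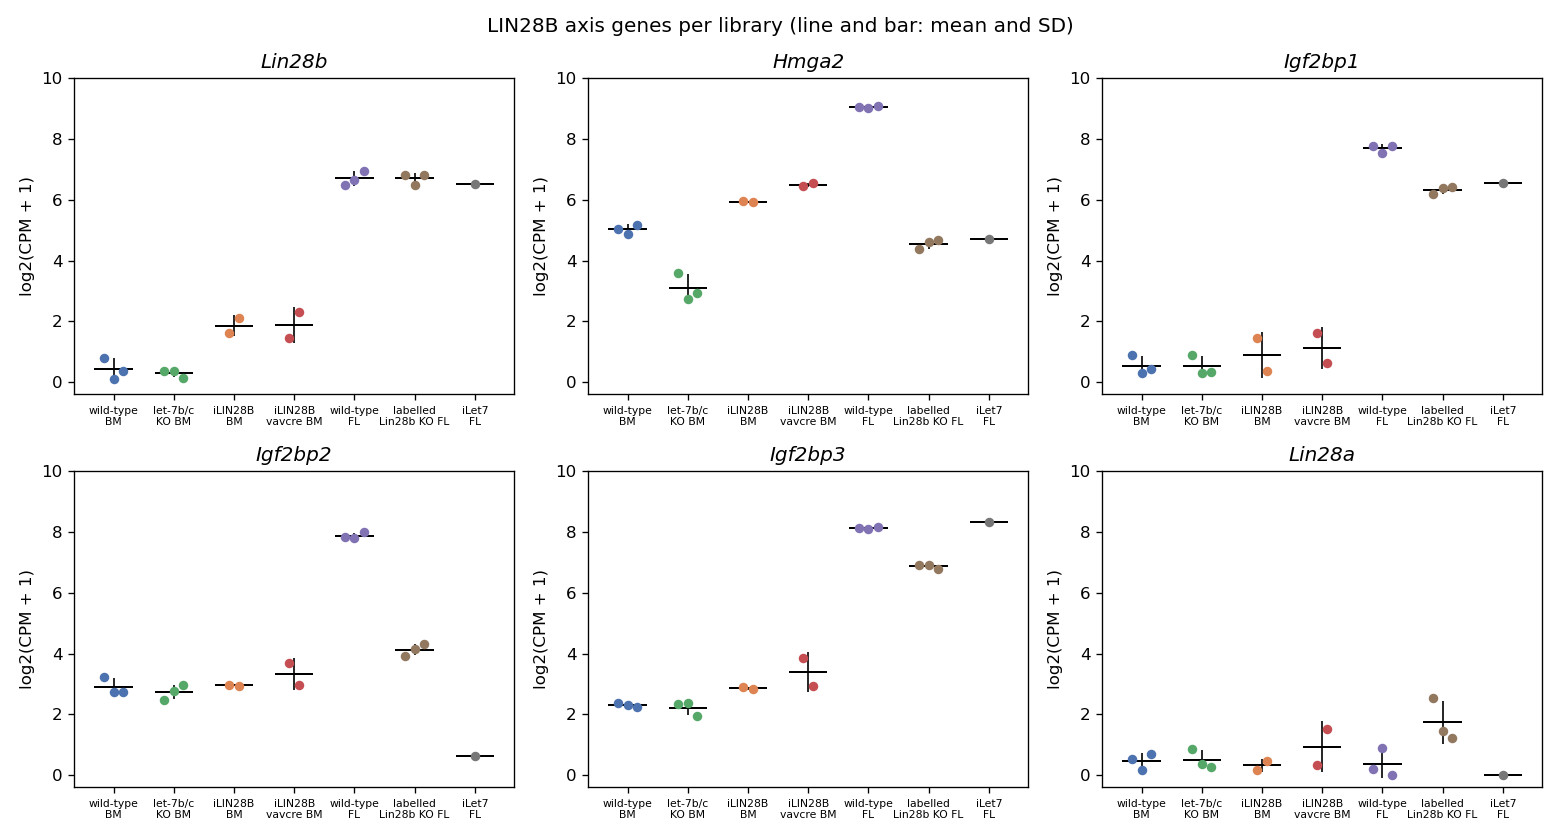
CPM of Lin28b, Hmga2, Igf2bp1, Igf2bp2, Igf2bp3 and Lin28a in each library, as log2(CPM + 1), by group (points are libraries, line and bar are the group's mean and SD). Lin28b stood at 104 CPM in both wild-type fetal liver and the libraries labelled Lin28b knockout, while Hmga2 stood at 533 and 22.6 CPM.

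Wild-type fetal liver progenitors differed from wild-type adult bone marrow progenitors by high levels of the LIN28B and let-7 axis genes, more messages of DNA replication, and far fewer of interferon response and MHC class I presentation genes. The oxidative phosphorylation list was also called higher and the granulocyte and megakaryocyte lists lower, but not with an estimated correlation (adjusted p = 0.0712 to 0.467). Of the 13558 genes tested, 1887 were higher and 1790 lower in fetal liver, 3677 in all (n = 3 and 3). At least 2-fold differences numbered 1236, of which 398 were higher and 838 lower. Apart from Lin28b (273-fold, adjusted p = 7.89e-09), the axis genes that rose were Hmga2, an architectural chromatin protein of fetal cells, and the RNA-binding proteins Igf2bp1, Igf2bp2 and Igf2bp3. Hmga2 rose from 31.9 ± 3.46 to 533 ± 11.2 CPM (16.7-fold, adjusted p = 9.24e-10), Igf2bp1 422-fold to 207 ± 19.7 CPM, Igf2bp2 35.8-fold to 236 ± 15.6 CPM and Igf2bp3 70.7-fold to 281 ± 6.69 CPM. Lin28a stayed under 1 CPM in either tissue (adjusted p = 0.911).

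The 6 tested axis genes passed the set test (5 higher and 0 lower, also when adjusted over the list alone, camera adjusted p = 8.52e-09). Of 41 tested let-7 targets, which include the axis genes, 21 rose and 4 fell (23 and 5 adjusted over the list alone, adjusted p = 2.30e-07). Of 14 imprinted and fetal growth genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.250 with an estimated correlation). Their median log2 change was 1.89, or 0.31 with the genes at 0 counts set at their bound. Among them Ndn rose 21.1-fold and Igf2r, the receptor that clears IGF2, 6.66-fold. Peg3 rose 218-fold, with a 95% counting interval of 60.45 to 1803 because adult marrow held 2 counts. Other large rises were those of Fscn1, which bundles actin (182-fold), Nes, the intermediate filament nestin (141-fold), Cdh17, a cadherin (58.45-fold), and Zfp711, a zinc finger protein (44.75-fold). Evc2, a ciliary protein of hedgehog signalling, stood at 19.1 ± 2.48 CPM in fetal liver against 1 count in all adult marrow libraries, a ratio of 1062 (95% counting interval 191 to 41950).

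Interferon response genes were lower in fetal liver almost as a block: of 30 tested, 0 rose and 24 fell (26 adjusted over the list alone, camera adjusted p = 1.08e-13). Lgals3bp fell from 190 ± 10.3 to 36.4 ± 5.20 CPM (5.20-fold), Oas3, a sensor of double-stranded RNA, 19.2-fold, and Ifi44 125-fold. MHC class I presentation followed, with 0 of 13 higher and 10 lower (10 adjusted over the list alone, adjusted p = 1.57e-12). H2-D1 fell from 870 ± 13.01 to 123 ± 7.51 CPM and H2-K1 7.55-fold, 2 near-identical genes whose shared reads make each value uncertain. Nlrc5, the transactivator of MHC class I genes, fell 61.2-fold to 0.745 ± 0.168 CPM.

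Among the markers of myeloid lineages, 17 of 25 granulocyte genes fell and 1 rose (19 and 1 adjusted over the list alone, adjusted p = 9.59e-05, and adjusted p = 0.467 with an estimated correlation). Ctsg, a protease of primary granules, fell 4.97-fold, Cd177, a neutrophil surface protein, 55.6-fold, and Chil3, a chitinase-like secreted protein, 131-fold. The matrix protease Mmp9 fell 141-fold and the siderophore-binding protein Lcn2 62.6-fold. Outside the list the protease inhibitor Slpi fell 83.4-fold and the dehydratase Sdsl 124-fold. Vcam1, an adhesion molecule, stood at 13.8 ± 5.32 CPM in adult marrow against 3 counts in all fetal liver libraries, a ratio of 266 (95% counting interval 91.1 to 1290). Of 19 megakaryocyte genes 11 fell and 0 rose (14 and 0 adjusted over the list alone, adjusted p = 0.000415, and adjusted p = 0.413 with an estimated correlation). The platelet chemokine Pf4 fell 11.01-fold, the integrin Itga2b 3.31-fold and Gata2 2.13-fold. Of 16 mast cell, basophil and eosinophil genes, 7 fell and 1 rose (the same numbers adjusted over the list alone, adjusted p = 0.0126, and adjusted p = 0.07645 with an estimated correlation). Slc18a2 fell 3.04-fold, the mast cell protease Cpa3 4.04-fold and Rgs1 5.52-fold. Lymphoid genes moved the other way, with 7 of 22 higher and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.00170, and adjusted p = 0.212 with an estimated correlation). Il7r, the receptor of early lymphoid cells, rose 17.4-fold and Rag2, a recombinase of antigen receptor genes, 5.44-fold. Rag1 stood at 9.55 ± 2.71 CPM against 1 count in adult marrow, a ratio of 530 (95% counting interval 95.1 to 20940).

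Erythroid genes were lower by count, with 6 of 29 lower and 1 higher (also adjusted over the list alone, adjusted p = 0.0318, and adjusted p = 0.608 with an estimated correlation). Icam4 fell 2.31-fold, Nfe2 2.35-fold and the water channel Aqp1 3.005-fold. That call ended without wild-type bone marrow library 5 (adjusted p = 0.138), fetal liver library 4 (0.0597) or fetal liver library 5 (0.134). Of 26 G1/S and DNA replication genes 16 rose and 1 fell (also adjusted over the list alone, adjusted p = 2.02e-06). The helicase subunit Mcm4 rose 1.58-fold, cyclin E1, Ccne1, 3.46-fold and Gins2 1.96-fold. Oxidative phosphorylation rose by small steps in 50 of 66 genes and fell in 0 (54 and 0 adjusted over the list alone, adjusted p = 3.435e-18, and adjusted p = 0.0712 with an estimated correlation). Sdhd stood at 1.65-fold, Atp5a1 at 1.56-fold and Atp5j2 at 1.62-fold. Glycolysis rose in 8 of 17 genes and fell in 0 (also adjusted over the list alone, adjusted p = 0.0002845, and adjusted p = 0.0583 with an estimated correlation). The glucose transporter Slc2a1 rose 3.985-fold, Pgk1 1.82-fold and Tpi1 1.88-fold. Ribosomal protein genes rose in 10 of 77 and fell in 3 (10 and 2 adjusted over the list alone, adjusted p = 0.00137, and adjusted p = 0.757 with an estimated correlation). Rps4l rose 6.00-fold, Rps27l 1.72-fold and Rps2 1.23-fold, and the list's call ended without wild-type bone marrow library 5 (adjusted p = 0.176). The other lists did not pass the set test: monocyte and dendritic (3 of 24 higher and 9 lower), stem and multipotent progenitor (2 of 22 and 3), hepatocyte (0 of 17 and 1), stroma and endothelium (0 of 13 and 4), G2/M (4 of 26 and 5), heme and iron (5 of 21 and 3), immediate early and heat shock (2 of 21 and 1) and cholesterol synthesis (0 of 20 and 1). Of these, counts differed when adjusted over the list alone for the monocyte and dendritic (4 higher and 9 lower), G2/M (6 and 5) and cholesterol synthesis (0 and 0) lists. The tissue and the developmental stage changed together in this comparison.

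Fetal liver libraries labelled Lin28b knockout differed from wild-type fetal liver by a large rise of erythroid and heme genes and by a fall of Hmga2 and Igf2bp2, although their Lin28b count did not differ. The liver, stromal, granulocyte and megakaryocyte lists were also called higher, but not with an estimated correlation (adjusted p = 0.260 to 0.600). Of 13558 genes, 2823 were higher and 3118 lower, 5941 in all (n = 3 and 3), and 3190 differed at least 2-fold (1807 higher and 1383 lower). With DESeq2 size factors 52.68% of 5852 calls were higher in place of 47.5%. Hmga2 fell from 533 ± 11.2 to 22.6 ± 2.65 CPM (23.5-fold, edgeR adjusted p = 3.46e-11), under the 31.9 CPM of wild-type adult marrow. Igf2bp2 fell 14.2-fold to 16.6 ± 2.31 CPM, Igf2bp1 2.59-fold to 79.9 ± 7.07 CPM and Igf2bp3 2.40-fold to 117 ± 5.55 CPM. Lin28a was 7.78-fold higher at 2.62 ± 1.93 CPM (adjusted p = 0.0381), a call that ended without labelled knockout library 3 (adjusted p = 0.163), wild-type fetal liver library 1 (0.127) or wild-type fetal liver library 5 (0.101).

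Of the axis list 4 genes fell and 1 rose (also adjusted over the list alone, camera adjusted p = 0.00285, and adjusted p = 0.0583 with an estimated correlation). The let-7 targets moved both ways, with 9 of 41 higher and 18 lower (10 and 18 adjusted over the list alone), and did not pass the set test (adjusted p = 0.0547), except without wild-type fetal liver library 4 (0.0449). Limma's fry test, which asks whether a list moves on balance 1 way and not whether it moves more than other genes, pointed down (9.79e-09). Mycn, a let-7 target chosen after its values were seen, fell 12.1-fold. Other large falls were those of Jag2, a Notch ligand (18.2-fold), Shisa8 (17.2-fold), Zfp711 (15.65-fold), Lrrn4 (14.5-fold), the T cell coreceptor Cd4 (13.4-fold) and the carbonic anhydrase Car12 (13.4-fold).

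Erythroid genes rose together, 28 of 29 higher and 0 lower (also adjusted over the list alone, camera adjusted p = 4.56e-22), with a median log2 change of 5.67 (5.67 with the gene at 0 counts set at its bound). Fech, which inserts iron to form heme, rose from 107 ± 17.1 to 5428 ± 424 CPM (50.8-fold), the mitochondrial iron carrier Slc25a37 103-fold and Icam4 23.2-fold. The red cell regulators Gata1 and Klf1, chosen after their values were seen, rose from 107 ± 4.15 to 483 ± 16.5 CPM and from 72.8 ± 8.60 to 1120 ± 47.9 CPM. All 3 tested embryonic globins rose. Hbb-y stood at 2862 ± 1764 CPM against 2.88 ± 2.91 CPM (991-fold) and Hba-x was 1123-fold higher, with reads that similar globin genes may share. Heme and iron genes rose in 18 of 21 and fell in 0 (19 and 0 adjusted over the list alone, adjusted p = 1.62e-17). Urod rose 12.4-fold, the transporter Abcb10 14.5-fold and the ferritin chain Ftl1 5.36-fold.

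Liver cell messages were present in all 3 libraries labelled Lin28b knockout, at levels that differed between them. Of 17 hepatocyte genes 16 rose and 1 fell (also adjusted over the list alone, adjusted p = 9.78e-06, and adjusted p = 0.412 with an estimated correlation). Their median log2 change was 7.34, or 6.81 with genes at 0 counts set at their bound. Alb, serum albumin, stood at 255 ± 165 CPM against 0.499 ± 0.182 CPM, with single libraries from 110 to 435 CPM. Afp stood at 286 ± 169 CPM against 2.55 ± 0.876 CPM and Apoa1 at 76.1 ± 49.1 against 0.410 ± 0.182 CPM. The member that fell was Hnf4a, a transcription factor of hepatocytes named after its values were seen, at 7.87 ± 5.93 against 25.6 ± 1.46 CPM. Serpina6, a liver-secreted carrier of steroid hormones, stood at 58.0 ± 36.6 CPM against 3 counts in wild-type fetal liver, a ratio of 1123 (95% counting interval 384 to 5443). The liver gene Itih3 was at least 215-fold higher and the class I gene H2-Q10 at least 213.5-fold higher, against a floor of 3 counts over the wild-type group. Stromal and endothelial genes rose in 11 of 13 and fell in 0 (12 and 0 adjusted over the list alone, adjusted p = 0.000154, and adjusted p = 0.260 with an estimated correlation). Vcam1 stood at 68.4 ± 12.4 CPM against 3 counts, a ratio of 1324 (453 to 6421), Bgn was at least 88.7-fold higher, and Cxcl12 stood at 4.08 ± 1.54 CPM against 2 counts, a ratio of 118 (32.8 to 978, both 95% counting intervals). Mmel1, a membrane endopeptidase, stood at 18.6 ± 3.82 CPM against 1 count, a ratio of 1082 (95% counting interval 194 to 42750).

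Markers of mature myeloid cells rose in the same libraries. Of 25 granulocyte genes 20 rose and 0 fell (20 and 1 adjusted over the list alone, adjusted p = 9.90e-05, and adjusted p = 0.467 with an estimated correlation). Lcn2 rose 254-fold, the granule protein Ltf, lactoferrin, 113.5-fold and Cd177 116-fold. Megakaryocyte genes rose in 12 of 19 and fell in 4 (also adjusted over the list alone, adjusted p = 0.0215, and adjusted p = 0.600 with an estimated correlation). The platelet chemokines Ppbp and Pf4 rose 901-fold and 62.4-fold and the integrin Itgb3 7.29-fold. Monocyte and dendritic genes rose in 10 of 24 and fell in 1 (also adjusted over the list alone, adjusted p = 0.00597, and adjusted p = 0.408 with an estimated correlation). Ly6c2 rose 63.2-fold and Zbtb46 9.50-fold. H2-Aa stood at 7.44 ± 1.09 CPM against 3 counts, a ratio of 144 (95% counting interval 49.3 to 698.5). G2/M genes rose in 24 of 26 and fell in 0 (also adjusted over the list alone, adjusted p = 5.37e-15, and adjusted p = 0.0756 with an estimated correlation). The proliferation marker Mki67 rose from 682 ± 7.25 to 4896 ± 340 CPM, Ube2c 7.998-fold and Hmmr 2.96-fold.

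Stem and multipotent progenitor genes fell, 11 of 22 lower and 2 higher (11 and 3 adjusted over the list alone, adjusted p = 0.00369, and adjusted p = 0.260 with an estimated correlation). The cytokine receptor Flt3 fell 10.6-fold, the transcription factor Hlf 7.57-fold and Gata2 5.315-fold. MHC class I genes fell further, 8 of 13 lower and 1 higher (also adjusted over the list alone, adjusted p = 0.000837, and adjusted p = 0.0772 with an estimated correlation). The immunoproteasome subunit Psmb8 fell 5.07-fold, Erap1 2.50-fold and the peptide transporter Tap2 2.41-fold. Imprinted and fetal growth genes rose in 6 of 14 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0266, and adjusted p = 0.304 with an estimated correlation). Meg3 rose 125-fold, Plagl1 41.25-fold and Peg3 4.20-fold. Oxidative phosphorylation rose in 29 of 66 and fell in 11 (30 and 12 adjusted over the list alone, adjusted p = 0.0152, and adjusted p = 0.608 with an estimated correlation). Uqcr11 stood at 1.67-fold and Ndufv1 at 1.51-fold. The remaining lists did not pass: lymphoid (1 of 22 higher and 7 lower), mast cell (8 of 16 and 4), G1/S (7 of 26 and 3), interferon response (5 of 30 and 9), ribosomal protein (2 of 77 and 10), immediate early (8 of 21 and 3), glycolysis (4 of 17 and 5) and cholesterol synthesis (3 of 20 and 3). Adjusted over the list alone these became 8 higher and 5 lower for mast cell, 6 and 3 for G1/S, 5 and 10 for interferon response, 2 and 4 for ribosomal protein, 8 and 4 for immediate early and 3 and 2 for cholesterol synthesis genes. Because Lin28b itself did not fall, no direction here can be tied to a measured loss of Lin28b.

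**Figure D2:**
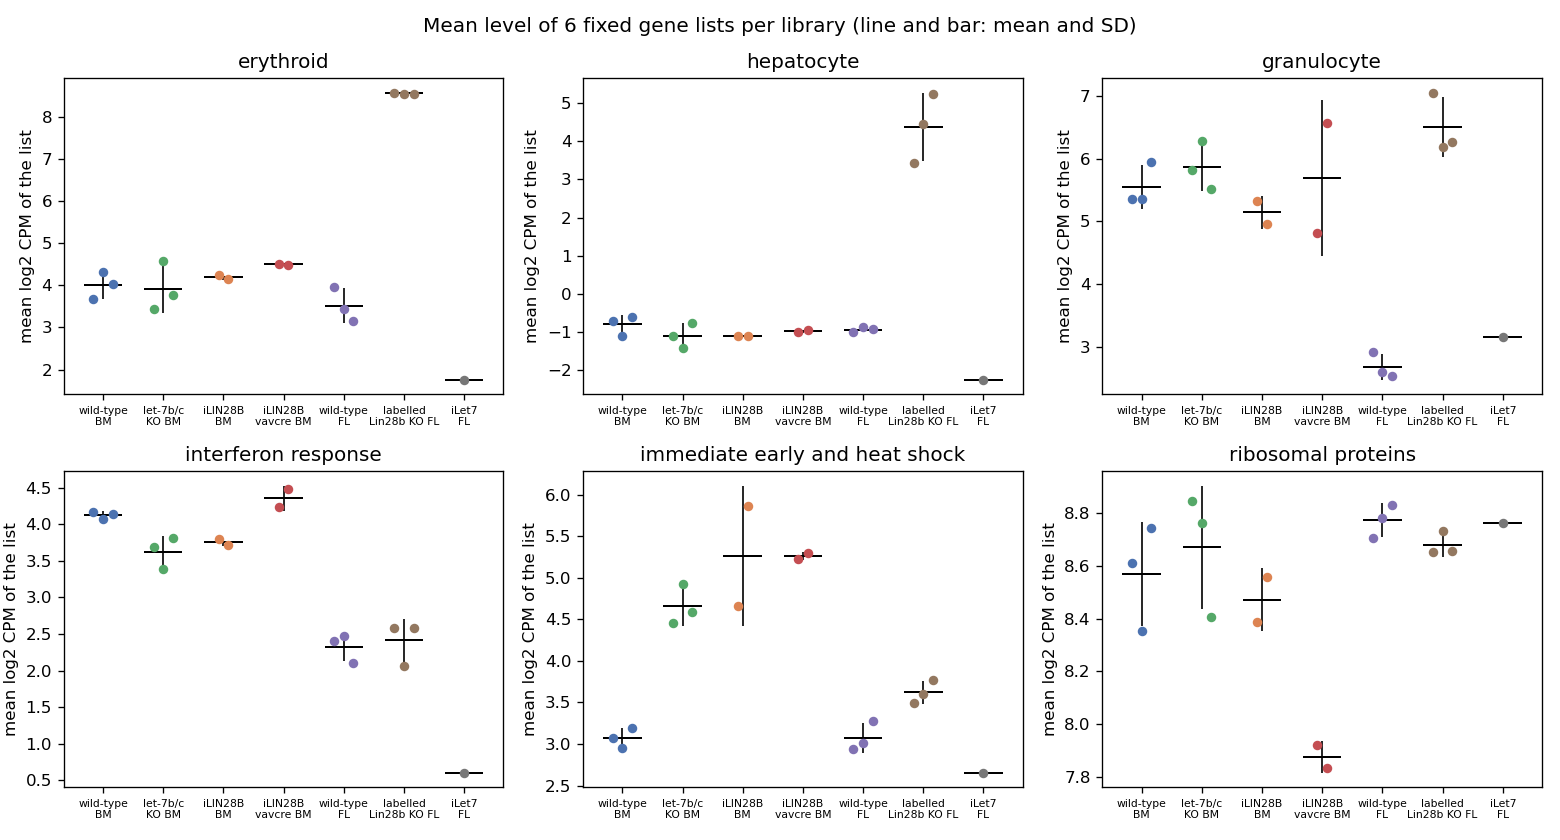
Mean log2 CPM over the members of 6 fixed gene lists in each library, by group (points are libraries, line and bar are the group's mean and SD, and each panel has its own vertical range). The erythroid and hepatocyte lists were high in the 3 libraries labelled Lin28b knockout, and the immediate early and heat shock list stood at 3.07 in wild-type bone marrow, 5.26 in either LIN28B line and 4.66 in the let-7b/c knockout.

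LIN28B marrow libraries had modestly higher Hmga2 and much higher immediate early genes than wild-type ones. Only the line with vavcre had called falls of ribosomal protein and rises of cell cycle genes. With an estimated correlation the ribosomal and G2/M calls in the lines' mean ended (camera adjusted p = 0.2695 and 0.408). In this mean (4 libraries) against wild-type bone marrow (n = 3), 893 genes were higher and 1065 lower, 1958 in all. Of these, 557 differed at least 2-fold (100 higher and 457 lower). Of the 1958, 998 had no overlap between LIN28B and wild-type libraries. Lin28b rose from 0.359 ± 0.351 to 2.75 ± 1.03 CPM (7.24-fold, edgeR adjusted p = 0.00133), counts that may miss the induced LIN28B. Hmga2 rose from 31.9 ± 3.46 to 74.6 ± 16.8 CPM (2.29-fold, adjusted p = 0.000359) and Igf2bp3 from 3.96 ± 0.249 to 8.13 ± 3.59 CPM (1.99-fold, adjusted p = 0.00463). Igf2bp1 (adjusted p = 0.216), Igf2bp2 (0.418) and Lin28a (0.851) did not pass. Of the axis list 3 genes rose and 0 fell (also adjusted over the list alone, camera adjusted p = 0.002215, and adjusted p = 0.0583 with an estimated correlation). Of 41 let-7 targets 16 rose and 1 fell (19 and 3 adjusted over the list alone, adjusted p = 4.06e-08), including the GTPase Nras (1.44-fold), Arid3b (2.18-fold) and the helicase-nuclease Dna2 (1.57-fold).

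The immediate early and heat shock list had 16 of 21 genes higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 7.63e-18), with a median log2 change of 2.02, or 1.86 with the gene at 0 counts set at its bound. Fos rose from 1.60 ± 0.486 to 95.3 ± 54.3 CPM (59.0-fold) and Jun from 15.9 ± 2.74 to 683 ± 219 CPM (42.8-fold). Further rises were those of the transcription factors Egr1 (18.3-fold) and Junb (4.35-fold), the phosphatase Dusp1 (11.3-fold), and the near-identical chaperones Hspa1a (14.0-fold) and Hspa1b (9.22-fold), whose reads cannot be assigned with certainty. Cstdc5, of the stefin protease inhibitor family with several similar copies, stood at 68.0 ± 54.5 CPM with vavcre (403-fold) and 6.08 ± 7.38 CPM without it (35.45-fold, adjusted p = 0.0849) against 0.166 ± 0.238 CPM, a geometric mean of 119.5-fold.

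Ribosomal protein genes fell in 57 of 77 and rose in 2 (61 and 2 adjusted over the list alone, adjusted p = 3.435e-18, and adjusted p = 0.2695 with an estimated correlation). Line by line, 60 were lower and 2 higher with vavcre (62 and 2 adjusted over the list alone, median log2 change -0.84), while 0 were lower and 0 higher without vavcre (also adjusted over the list alone, median -0.14). On average over the lines the steps were small, such as 1.82-fold for Rpl36, 1.88-fold for Rpl39 and 1.54-fold for Rpl9. Monocyte and dendritic genes fell in 8 of 24 and rose in 1 (also adjusted over the list alone, adjusted p = 0.0288, and adjusted p = 0.447 with an estimated correlation). Ms4a6c fell 5.035-fold, Ly86 2.55-fold and Cd300c2 11.6-fold. That call ended without vavcre library 4 (adjusted p = 0.556) or LIN28B library 5 of the line without vavcre (0.0672). Other falls were those of Vcam1 (8.44-fold), Crebl2 (5.66-fold), the transporter Slc16a11 (5.475-fold), heme oxygenase Hmox1 (5.25-fold), Ms4a3 (4.90-fold), Ly6c2 (4.22-fold) and Alcam (3.88-fold). MHC class I genes fell in 3 of 13 and rose in 0 (8 and 1 adjusted over the list alone, adjusted p = 0.0160, and adjusted p = 0.220 with an estimated correlation). Erap1 fell 1.485-fold and Psme1 1.54-fold, and the list's call ended without wild-type bone marrow library 6 (adjusted p = 0.0543). With vavcre 5 were lower and 1 higher, without it 0 and 0 (7 and 1, and 1 and 0, adjusted over the list alone).

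Some cell cycle genes rose in the lines' mean (G2/M not with an estimated correlation), in single lines only with vavcre. There 8 of 26 G1/S genes rose and 1 fell and 11 of 26 G2/M genes rose and 1 fell (10 and 1, and 11 and 1, adjusted over the list alone), against 0 in either direction and either list without vavcre (also adjusted over the list alone). In the mean of the lines, of the G1/S list 6 of 26 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0002845), among them Mcm2 (1.38-fold), Rrm2 (1.499-fold) and Rfc4 (1.44-fold). Of the G2/M list 7 of 26 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.0113, and adjusted p = 0.408 with an estimated correlation). Plk1 rose 1.77-fold, Ccnb2 1.34-fold and Aurkb 1.30-fold, and the list's call ended without vavcre library 4 (adjusted p = 0.0575). Erythroid genes rose in 3 of 29 and fell in 0 (also adjusted over the list alone, adjusted p = 0.002215, and adjusted p = 0.354 with an estimated correlation), with Gata1 up 1.62-fold. With vavcre 6 rose and 1 fell, without it 2 and 0 (6 and 1, and 6 and 0, adjusted over the list alone). Oxidative phosphorylation rose in 10 of 66 and fell in 3 (11 and 5 adjusted over the list alone, adjusted p = 0.0314, and adjusted p = 0.649 with an estimated correlation). Uqcrc1 rose 1.57-fold and Sdha 1.23-fold. With vavcre 20 rose and 6 fell, without it 0 and 0 (20 and 10, and 0 and 0, adjusted over the list alone). The list's median log2 change was 0.04 and its mean -0.07 while the test pointed up, and the call ended without LIN28B library 1 of the line without vavcre (adjusted p = 0.0563), vavcre library 4 (0.11) or wild-type bone marrow library 5 (0.286). The remaining lists did not pass: imprinted and fetal growth (1 of 14 higher and 0 lower), megakaryocyte (0 of 19 and 3), granulocyte (0 of 25 and 4), lymphoid (1 of 22 and 0), mast cell (3 of 16 and 0), stem and multipotent progenitor (0 of 22 and 2), hepatocyte (0 of 17 and 0), stroma and endothelium (0 of 13 and 5), interferon response (2 of 30 and 3), heme and iron (6 of 21 and 2), glycolysis (1 of 17 and 0) and cholesterol synthesis (2 of 20 and 4). Adjusted over the list alone these became 0 higher and 6 lower for granulocyte, 4 and 2 for mast cell, 8 and 3 for heme and iron and 3 and 4 for cholesterol synthesis genes. Without vavcre library 4 the lymphoid (adjusted p = 0.00756) and heme and iron (0.04685) lists passed, without vavcre library 6 the granulocyte list (0.0201) and without wild-type bone marrow library 5 the heme and iron list (0.0495). The 1958 genes became 169 with the 4 libraries fitted as 1 group, 1132 with only the groups compared and 1278 with limma-voom quality weights, where 56.57% of calls were higher in place of 45.6%. They became 1166 without LIN28B library 1 of the line without vavcre, 1095 without wild-type bone marrow library 2 and 1206 without wild-type bone marrow library 6.

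The line without vavcre had fewer called genes. Without vavcre (n = 2) 69 genes were higher and 40 lower, with vavcre (n = 2) 1691 higher and 1943 lower, each against wild-type bone marrow (n = 3). Immediate early and heat shock genes rose in 14 of 21 without vavcre and 15 of 21 with it (16 and 15 adjusted over the list alone), with 0 lower in either. Of 41 let-7 targets 9 rose and 0 fell without vavcre and 17 rose and 3 fell with it (14 and 0, and 18 and 4, adjusted over the list alone). Fos rose 60.8-fold without vavcre and 57.2-fold with it, and Jun 44.4-fold and 41.3-fold. Without vavcre Hspa1a rose 20.1-fold, Hspa1b 14.9-fold, Dusp1 7.76-fold and the RNA-binding protein Zfp36 4.44-fold, while Ms4a6c fell 6.45-fold, the receptor kinase Met 5.51-fold and Ttc39c 4.74-fold. Hmga2 rose from 31.9 ± 3.46 to 60.2 ± 0.955 CPM without vavcre (1.89-fold, edgeR adjusted p = 0.0234), and that call ended in each fit that left out 1 of the 5 libraries, with adjusted p from 0.0522 to 0.172. Lin28b rose 7.06-fold without vavcre (adjusted p = 0.0177), a call that ended without LIN28B library 5 (adjusted p = 0.234), wild-type bone marrow library 5 (0.0581) or wild-type bone marrow library 6 (0.0893). With vavcre Hmga2 rose 2.79-fold to 89.0 ± 4.51 CPM (adjusted p = 3.61e-05), Igf2bp3 2.53-fold and Lin28b 7.42-fold. Stefin family genes were among the largest rises there, Cstdc5 at 403-fold, Stfa2l1 at 98.25-fold, Stfa1 at 78.7-fold and Cstdc4 at 38.1-fold, with reads that similar copies may share. Prss34, a basophil protease, rose 117-fold, a call that ended without vavcre library 6 (adjusted p = 0.501). The kinase Plk2 rose 20.4-fold, while the RNA-binding protein Lsm14b fell 20.3-fold, Crebl2 12.8-fold, Cdk18 10.97-fold, Vcam1 10.5-fold, Tanc2 9.50-fold, Slc16a11 9.30-fold and Smco4 7.495-fold. Without vavcre the 109 genes became 40 without LIN28B library 1, 26 without LIN28B library 5, and 62, 58 and 48 without wild-type bone marrow libraries 2, 5 and 6. They also became 191 with no filter, 403 with DESeq2, 335 with limma-voom quality weights, 268 with only the groups compared and 255 without the vavcre and inducible let-7 libraries. With vavcre the 3634 became 1428 with limma-voom quality weights (61.7% higher in place of 46.5%) and 2007 with only the groups compared.

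Set directly against each other, the LIN28B lines with and without vavcre differed in 2799 genes, 1270 higher and 1529 lower with vavcre (n = 2 and 2), 956 of them at least 2-fold (243 higher and 713 lower). No vavcre line without LIN28B was measured, so the comparison is one of lines and not of LIN28B effects alone. Neither Lin28b (adjusted p = 0.956), Hmga2 (1.48-fold, adjusted p = 0.0513) nor Igf2bp3 (1.61-fold, adjusted p = 0.0571) differed past the threshold. Ribosomal protein genes were lower with vavcre in 54 of 77 and higher in 2 (59 and 3 adjusted over the list alone, camera adjusted p = 3.35e-15, and adjusted p = 0.318 with an estimated correlation). Rpl36 was 2.81-fold lower, Rpl28 2.46-fold and Rpl8 2.13-fold. G2/M genes were higher in 12 of 26 and lower in 0 (also adjusted over the list alone, adjusted p = 2.30e-07, and adjusted p = 0.1375 with an estimated correlation). The mitotic kinases Plk1 and Aurkb were 2.53-fold and 1.65-fold higher and Hmmr 1.82-fold. G1/S genes were higher in 6 of 26 and lower in 0 (7 and 0 adjusted over the list alone, adjusted p = 0.00547, and adjusted p = 0.0583 with an estimated correlation). Rfc4 was 1.74-fold and Rrm2 1.70-fold higher, and the list's call ended without vavcre library 6 (adjusted p = 0.0853). Interferon response genes were higher in 8 of 30 and lower in 1 (11 and 3 adjusted over the list alone, adjusted p = 0.000292, and adjusted p = 0.187 with an estimated correlation). Ifi44 was 4.08-fold and Rtp4 2.685-fold higher. Granulocyte genes were higher in 3 of 25 and lower in 0 (also adjusted over the list alone, adjusted p = 0.0112, and adjusted p = 0.649 with an estimated correlation), with Igsf6 3.48-fold higher. Lymphoid genes were higher in 5 of 22 and lower in 0 (also adjusted over the list alone, adjusted p = 0.0319, and adjusted p = 0.376 with an estimated correlation). These calls ended without LIN28B library 5 (granulocyte adjusted p = 0.0532, lymphoid 0.111) or vavcre library 6 (0.926 and 0.344). Of single genes the sterol transporter Abcg4 (22.5-fold), Stfa2l1 (21.4-fold) and Cstdc4 (10.4-fold) were higher, and Lsm14b (16.4-fold), Cdk18 (14.1-fold), Zfp831 (10.8-fold), Tanc2 (8.52-fold) and Tspo2 (8.38-fold) lower. The remaining lists did not pass: axis (0 of 6 higher and 0 lower), let-7 targets (4 of 41 and 5), imprinted and fetal growth (0 of 14 and 1), erythroid (4 of 29 and 4), megakaryocyte (1 of 19 and 3), monocyte and dendritic (5 of 24 and 2), mast cell (0 of 16 and 6), stem and multipotent progenitor (0 of 22 and 4), hepatocyte (1 of 17 and 0), stroma and endothelium (0 of 13 and 1), MHC class I (0 of 13 and 4), heme and iron (3 of 21 and 4), oxidative phosphorylation (16 of 66 and 9), immediate early (2 of 21 and 2), glycolysis (1 of 17 and 1) and cholesterol synthesis (0 of 20 and 6). Adjusted over the list alone these became 2 higher and 0 lower for the axis, 6 and 5 for let-7 targets, 0 and 0 for imprinted, 6 and 4 for erythroid, 0 and 5 for MHC class I, 4 and 5 for heme and iron, 17 and 10 for oxidative phosphorylation and 1 and 6 for cholesterol synthesis genes. Without LIN28B library 1 the mast cell (adjusted p = 0.0338) and oxidative phosphorylation (0.0286) lists passed, without LIN28B library 5 the immediate early list (0.000652) and without vavcre library 4 the monocyte (0.00311) and cholesterol synthesis (0.004753) lists. The 2 vavcre libraries stood apart in other ways. Xist, transcribed from the inactive X chromosome of females, was at 168 ± 6.13 CPM against 1.46 ± 0.771 CPM. Genes with a count numbered 12079 and 12635 against 13786 and 13882, and 45S ribosomal RNA took 0.138% and 0.165% of counts against 1.03% and 1.85%. The 2799 genes became 1376 without LIN28B library 5, 1056 with limma-voom quality weights (58.5% higher in place of 45.4%) and 422 with only the groups compared.

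In let-7b/c knockout libraries from adult marrow, monocyte genes, led by the chemokine receptor Ccr2, were higher than in wild-type libraries and Hmga2 was lower. The immediate early list was also called higher and the megakaryocyte list lower, but not with an estimated correlation (adjusted p = 0.0772 and 0.2155). Against wild-type bone marrow 180 genes were higher and 125 lower, 305 in all (n = 3 and 3), and 117 differed at least 2-fold (75 higher and 42 lower). Ccr2 rose from 59.7 ± 9.26 to 1471 ± 205 CPM (24.65-fold, edgeR adjusted p = 0.000579). Hmga2, a let-7 target, fell from 31.9 ± 3.46 to 7.80 ± 2.89 CPM (4.09-fold, adjusted p = 2.79e-05). No other axis gene passed, with adjusted p of 0.709 for Lin28b, 0.976 for Lin28a, 0.981 for Igf2bp1, 0.740 for Igf2bp2 and 0.892 for Igf2bp3. Of 41 let-7 targets 1 rose and 3 fell (2 and 4 adjusted over the list alone), and neither they (camera adjusted p = 0.139) nor the axis list (0.0939) passed the set test. The axis list passed, pointing down, without knockout library 1 (adjusted p = 0.0427) or wild-type bone marrow library 5 (0.0316), and limma's fry test of a balance within the list pointed down for both (adjusted p = 0.00746 for the axis list and 0.003585 for the targets). Mycn fell 3.44-fold.

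Monocyte and dendritic genes rose in 7 of 24 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 1.51e-13). Besides Ccr2, the growth factor receptor Csf1r rose from 101 ± 10.6 to 260 ± 66.5 CPM (2.565-fold) and the class II gene H2-Ab1 2.32-fold. Immediate early and heat shock genes rose in 10 of 21 and fell in 0 (13 and 0 adjusted over the list alone, adjusted p = 1.13e-12, and adjusted p = 0.0772 with an estimated correlation). Fos rose 50.8-fold, Jun 26.5-fold to 422 ± 27.2 CPM, Hspa1a 16.0-fold and Dusp1 5.71-fold. Other large rises were the noncoding RNA Lncppara (133-fold), the IgE receptor chain Fcer1a (24.0-fold), the chemokine receptor Ccr1 (17.4-fold) and the anion transporter Slc26a1 (54.1-fold), the last lost without wild-type bone marrow library 2 (adjusted p = 0.0642). Megakaryocyte genes fell in 7 of 19 and rose in 0 (10 and 1 adjusted over the list alone, adjusted p = 8.52e-09, and adjusted p = 0.2155 with an estimated correlation). Cavin2 fell 3.57-fold and the thrombin receptor F2rl2 3.23-fold. Their median log2 change was -0.87, or -0.79 with the gene at 0 counts set at its bound. Plxdc2 fell 10.5-fold, the polycomb protein Cbx7 7.08-fold and the guanylate cyclase subunit Gucy1a1 5.86-fold.

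Interferon response genes fell in 2 of 30 and rose in 0 (4 and 0 adjusted over the list alone, adjusted p = 4.94e-06, and adjusted p = 0.153 with an estimated correlation), with Oasl2 down 4.43-fold. Stem and multipotent progenitor genes fell in 3 of 22 and rose in 0 (also adjusted over the list alone, adjusted p = 0.00372, and adjusted p = 0.260 with an estimated correlation). G1/S genes rose in 2 of 26 and fell in 0 (5 and 0 adjusted over the list alone, adjusted p = 0.00424, and adjusted p = 0.0583 with an estimated correlation), while G2/M genes fell in 1 and rose in 0 (2 and 0 adjusted over the list alone, adjusted p = 0.00372, and adjusted p = 0.467 with an estimated correlation). Oxidative phosphorylation passed with 1 of 66 higher and 0 lower (also adjusted over the list alone, adjusted p = 1.76e-06, and adjusted p = 0.296 with an estimated correlation). So did ribosomal protein genes with 1 of 77 and 0 (also adjusted over the list alone, adjusted p = 0.00424, and adjusted p = 0.796 with an estimated correlation), and glycolysis with 1 of 17 and 0 (also adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.200 with an estimated correlation). Granulocyte genes passed with 2 of 25 and 0 (also adjusted over the list alone, adjusted p = 0.00790, and adjusted p = 0.649 with an estimated correlation). Erythroid genes fell in 5 of 29 and rose in 0 (5 and 1 adjusted over the list alone, adjusted p = 0.0266, and adjusted p = 0.596 with an estimated correlation). Icam4 fell 1.89-fold and the cofactor Zfpm1 1.74-fold, and the list's median log2 change was -0.12 (-0.08 with the gene at 0 counts set at its bound) and its mean 0.05 while the test pointed down. Single libraries decided several of these calls. Without knockout library 1 the erythroid (adjusted p = 0.553), ribosomal protein (0.821) and glycolysis (0.0677) calls ended, without knockout library 2 the granulocyte (0.1445) and ribosomal protein (0.116) calls, and without knockout library 3 the erythroid (0.08025) and G2/M (0.231) calls. Without wild-type bone marrow library 2 the granulocyte call ended (0.0617), without library 5 the erythroid (0.228), granulocyte (0.0908) and ribosomal protein (0.864) calls, and without library 6 the G2/M call (0.0521). The remaining lists did not pass: imprinted and fetal growth (0 of 14 higher and 0 lower), lymphoid (0 of 22 and 0), mast cell (4 of 16 and 2), hepatocyte (0 of 17 and 1), stroma and endothelium (0 of 13 and 0), MHC class I (0 of 13 and 0), heme and iron (1 of 21 and 0) and cholesterol synthesis (1 of 20 and 0). Adjusted over the list alone these became 8 higher and 4 lower for mast cell and 2 and 2 for heme and iron genes. The knockout mice were of another strain by the labels (albino black 6 against C57BL/6J) and their libraries expressed Xist (191 ± 34.7 against 0.233 ± 0.0509 CPM), so strain, sex and genotype cannot be told apart. The short names of these libraries do not name bone marrow and could be read as another tissue, so the tissue rests on the labels, with positions (0.232 on average) near wild-type bone marrow. The 305 genes became 130 without knockout library 2, 96, 191 and 142 without wild-type bone marrow libraries 2, 5 and 6, 783 with DESeq2, 475 with limma-voom quality weights and 626 without the vavcre and inducible let-7 libraries.

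The inducible let-7 library from fetal liver, with no replicate and no test, kept Lin28b and held little Hmga2. Lin28b stood at 91.2 CPM, within the 89.3 to 124 CPM of the 3 wild-type fetal liver libraries. Hmga2 stood at 25.2 CPM against 533 ± 11.2 CPM (21.02-fold lower) and Igf2bp2 at 0.543 CPM against 236 ± 15.6 CPM, while Igf2bp1 stood at 93.6 CPM against 207 ± 19.7 CPM and Igf2bp3 at 320 CPM against 281 ± 6.69 CPM. Lin28a had 0 counts. Of 5530 genes at 30 CPM or more in this library or in wild-type fetal liver, 2955 lay above and 2127 below the range of the 3 wild-type libraries. The largest excesses were those of Ms4a3, a protein of granulocyte and monocyte progenitors (365 against 7.71 ± 2.92 CPM), Epha2, an ephrin receptor (57.8 against 1.11 ± 0.533 CPM), Zfp30 (53.4 against 2.11 ± 0.138 CPM) and neutrophil elastase, Elane (409 against 17.85 ± 5.92 CPM). Il31ra, Dixdc1, Il22ra2 and Cc2d2a stood at 47.8, 37.4, 30.4 and 80.8 CPM. Fastkd1 and Fstl1 had 0 counts, which allows up to 0.116 CPM, against 47.2 ± 2.74 and 36.2 ± 0.857 CPM in wild-type fetal liver. Rbm19, Rnf19b and Cep97 had 1 count each and Ccdc8 had 3, against 67.1 ± 3.57, 36.3 ± 2.52, 35.02 ± 3.29 and 60.3 ± 2.39 CPM. The library detected 10144 genes, fewer than any other, and 48 of 6692 genes at 10 CPM or more in wild-type fetal liver had 0 counts in it. Median log2 differences from wild-type fetal liver, with the percentile among 10000 random lists of matched level, were -1.05 for let-7 targets (0.26), -1.72 for erythroid (0), -3.32 for lymphoid (0.01), -1.74 for megakaryocyte (0.69), 0.70 for granulocyte (99.96) and 0.56 for oxidative phosphorylation genes (100). The axis list, at -1.31, lay at percentile 31.97, the stem and multipotent progenitor list, at -0.95, at 25.15, and the other 14 lists at 5.04 to 97.03. With genes at 0 counts set at their bound, the let-7 target median was -0.95 and the lymphoid median -3.12. These percentiles describe 1 library and not a condition.

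Each library was placed on the line between the wild-type profiles of marrow (0) and fetal liver (1) over all tested genes. Wild-type libraries, each placed without itself, averaged 0.150 ± 0.0249 in marrow and 0.890 ± 0.0311 in fetal liver (n = 3 each). The LIN28B libraries averaged 0.292 ± 0.0434 (n = 4), 0.142 above wild-type marrow (two-sided exact permutation p = 0.0286, the smallest that 4 against 3 allows). All 4 lay above all 3 wild-type libraries, at 0.2499 to 0.265 without vavcre and 0.306 to 0.346 with it. They detected fewer genes (12079 to 13882 against 13922 to 15644), an effect not tested. The let-7b/c knockout averaged 0.232 ± 0.0290 (n = 3), 0.0821 above wild-type marrow, and the libraries labelled Lin28b knockout 0.624 ± 0.0247 (n = 3), a difference from wild-type fetal liver of -0.266, each with exact permutation p = 0.1, the smallest that 3 against 3 allows. The inducible let-7 library stood at 0.883. In simulated data, LIN28B libraries made at 0 and at 0.5 were placed 0.0021 and 0.384 above wild-type marrow.

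**Figure D3:**
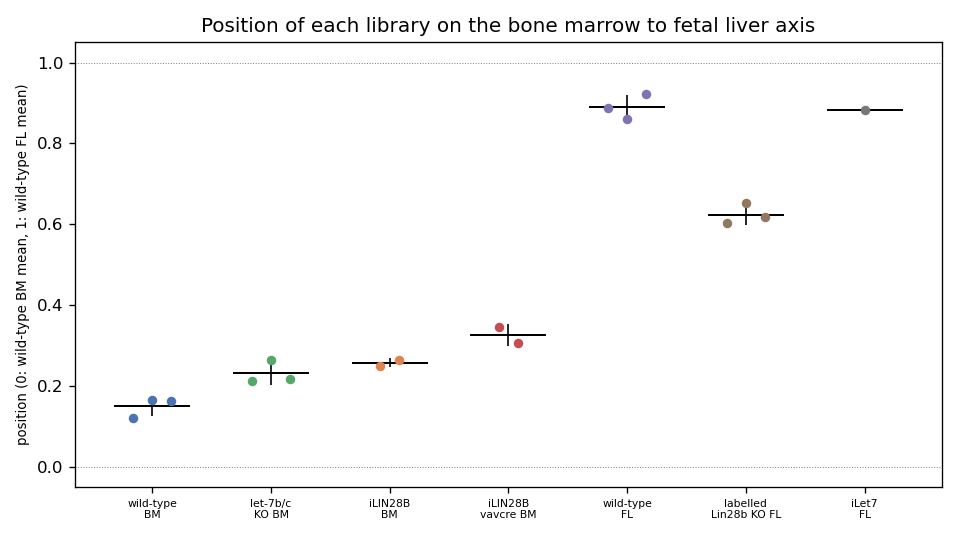
Position of each library between the mean profiles of wild-type bone marrow (0) and wild-type fetal liver (1), by group (points are libraries, line and bar are the group's mean and SD). The 4 LIN28B libraries, averaging 0.292, lay above the 3 wild-type bone marrow libraries, averaging 0.150, and the libraries labelled Lin28b knockout averaged 0.624.

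Genes shared between comparisons were counted by direction. Of 887 genes called in both the developmental and the LIN28B comparison, 705 moved the same way, Hmga2 and Igf2bp3 among them, with 420 higher in both (124 for independent lists) and 285 lower in both (141). Correlation and covariance of log2 changes across genes were 0.381 and 0.7365, against 0.529 and 0.348 in simulated groups without effect sharing wild-type marrow controls. For development and the let-7b/c knockout, 128 of 171 shared calls moved the same way (65 higher in both with 25.1 for independent lists, 63 lower with 16.5), with a correlation of 0.322 (0.507 simulated) and a covariance of 0.5245 (0.352 simulated). LIN28B induction and the let-7b/c knockout shared 115 calls, 79 in the same direction (49 higher with 11.9 for independent lists, 30 lower with 9.82), with a correlation of 0.313 (0.528 simulated) and a covariance of 0.465 (0.352 simulated). For development and the libraries labelled Lin28b knockout, 1445 of 2277 shared calls were opposite in direction. Of these, 804 were high in wild-type fetal liver and lower in the labelled libraries (434 for independent lists), and 641 the reverse (373). Their correlation was -0.291 (-0.496 simulated) and their covariance -0.848 (-0.327 simulated). No simulated overlap of calls exceeded 0. Of comparisons that share no library, the libraries labelled Lin28b knockout and LIN28B induction had 557 shared calls in the same and 557 in opposite directions (r = -0.0497 across genes). Of these, 251 were higher in both (186 for independent lists), 306 lower in both (245), 338 lower in the labelled libraries and higher after induction (205) and 219 the reverse (222). The libraries labelled Lin28b knockout and the let-7b/c knockout shared 212 calls (r = 0.0404 across genes). Of these, 53 were higher in both (37.5), 59 lower in both (28.7), 64 lower in the labelled libraries and higher in the let-7b/c knockout (41.4) and 36 the reverse (26). Genes are not independent replicates. The 3 shared controls, not split since 1 library would be left on a side, may give part of the relation.

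Genes whose 3′ UTR holds the let-7 seed match CTACCTCA were compared with other genes to ask whether let-7 targets as a class moved. Of 12387 tested genes with an annotated 3′ UTR, 609 held the 8-mer. After LIN28B induction their mean log2 change was 0.12 above that of other genes (camera adjusted p = 0.167 over 5 comparisons), rank 7 from the top among 420 8-mers of the same base composition. The set did not pass in the other comparisons either. In wild-type fetal liver against marrow the difference was 0.15 (adjusted p = 0.891, rank 4), in the libraries labelled Lin28b knockout -0.10 (adjusted p = 0.904, rank 283), in the let-7b/c knockout -0.00 (adjusted p = 0.891, rank 74) and between the LIN28B lines -0.04 (adjusted p = 0.891, rank 167). In the inducible let-7 library genes with the match lay -0.36 from the others, rank 18 from the bottom of 420, with no test. In simulations of LIN28B induction only, unadjusted camera p called 20 of 20 log2 shifts of 0.3 and 0 of 20 without. The real unadjusted p was 0.03335.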

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

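Tests of other cells in the libraries labelled Lin28b knockout, of low let-7 activity, of the level of wild-type bone marrow and of calls among genes of low level were chosen only after the result was seen, and the removal of GC and length trends was added after the data, but not its own result, were seen.

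In the libraries labelled Lin28b knockout, erythroid, heme and liver cell genes rose while Hmga2 fell. Dilution of progenitor RNA by other cells stays open as a part of the fall of Hmga2. The values that follow argue against it as the whole cause, unless the other cells expressed the genes compared. Of 22 stem and multipotent progenitor genes 0 fell as far. The lowest, Flt3, fell by a log2 change of 3.40 (SE 0.19) against 4.56 (SE 0.18) for Hmga2, and of 4031 genes at 50 CPM or more in wild-type fetal liver only Hmga2 itself fell that far. Hepatocytes or erythroid precursors in the sorted fraction and the labelled genotype cannot be told apart, as either could raise these genes in each library. Of 17 hepatocyte markers 16 rose and Hnf4a fell (7.87 against 25.6 CPM). The erythroid median log2 change was 5.67 (quartiles 3.07 to 7.27).

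Immediate early and heat shock genes rose over wild-type in LIN28B and let-7b/c knockout marrow (knockout camera adjusted p = 0.0772 with an estimated correlation). Wild-type bone marrow libraries low by themselves stay open, since their mean log2 CPM of 3.07 lay under every other marrow group (4.66 to 5.26). The 3.07 of fetal liver gives no level to expect in marrow. Against low let-7 activity by itself, the list had a median log2 change of -0.0304 (quartiles -0.336 to 0.120) in wild-type fetal liver, where 21 of 41 let-7 targets were higher and 4 lower (camera adjusted p = 2.30e-07), and 1.05 in the let-7b/c knockout; but let-7 was not measured, genes with its seed match did not pass there (adjusted p = 0.891) and tissue and stage differ, so it stays open. Other handling days or batches and the genotypes cannot be told apart either, with no day or batch in the labels. Heat shock members had a median log2 change of 1.94 after LIN28B induction. Hspa1a and Hspa1b stood at 3.80 and 3.20 there and 4.0023 and 3.19 in the let-7b/c knockout, while Dnajb1 stood at 0.69 and -0.08 (adjusted p = 0.871 for the latter) and Hsph1 passed in neither (0.26, adjusted p = 0.444, and -0.40, adjusted p = 0.432).

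The LIN28B lines with and without vavcre differed in 2799 genes, by a test of the difference itself, and the median log2 difference of the ribosomal protein list was -0.6702. Calls fell on 37.33% of the third of genes with the highest level (933 higher, 754 lower), with a spread pooled over groups. Only the groups compared gave 422 calls in all, so few molecules in the vavcre libraries stay open. Of the 293 calls among the 4520 genes of lowest level 256 (87.37%) were lower, which few molecules or the line could cause. GC content or transcript length bias is excluded, since 86.46% of calls stayed in the same direction once both trends were removed (ribosomal median -0.6685). Genes on X or Y made up 3.144% of calls and 3.231% of tested genes. With so few tested genes there, they could not have been most of the calls, so this share tests nothing further. Effects of sex on other genes, of where LIN28B was induced and of a batch stay open and untested, with 2 libraries on each side.

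Hmga2 fell in the let-7b/c knockout and rose after LIN28B induction, each against the same wild-type bone marrow libraries. These effects differed by a log2 value of -3.2276 (SE 0.18, edgeR adjusted p = 8.28e-08). In all, 2506 genes differed between these effects, 1422 higher and 1084 lower in the knockout. Ccr2 differed by 6.57 and Csf1r by 2.16 in log2 value. For the 2506, the part of the vavcre line (3634 calls, 109 without it) in the LIN28B mean was not tested. Knockout and induction were both set up to lower let-7 activity, and no test here separates genotype from strain and sex.

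Reads placed at more than 1 genome position, which no comparison uses, numbered 37.79 ± 3.09 per 100 uniquely placed in the libraries labelled Lin28b knockout (n = 3) and 15.25 ± 0.44 in wild-type fetal liver (n = 3). The other groups had 11.54 to 15.9. The counts do not say from which genes these reads came.

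Other splits of the same libraries were counted for the comparisons with at least 3 libraries on each side. For wild-type fetal liver against bone marrow the real split called 3677 genes and the highest of the others 1, for the libraries labelled Lin28b knockout 5941 and 0, and for the let-7b/c knockout 305 and 0. In each, 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. For LIN28B induction 3 of 35 splits, the real one included, gave as many genes as the real 169 (all 4 LIN28B libraries fitted as 1 group), so chance is not excluded. The highest, 1349, left LIN28B library 1 together with both vavcre libraries, and the next, 764, left wild-type bone marrow library 5 with them. What lies behind these counts, several times the real one, was not tested. Standing together of the vavcre libraries does not account for the counts alone, since these libraries also made up a side with LIN28B library 5 (13 genes), wild-type bone marrow library 6 (3) and wild-type bone marrow library 2 (0).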

How the results depend on the processing

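The fits with single-transcript genes only and those without the inducible let-7 or vavcre libraries were chosen after seeing the data. With DESeq2 size factors, with single-transcript genes only and without the inducible let-7 library, all 7 counts of called genes stayed within 1.5 times their value, but with DESeq2 size factors 52.68% of calls in the libraries labelled Lin28b knockout were higher in place of 47.5%. The cause was not tested for any change below unless a construction is named.

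Without a filter the LIN28B line without vavcre had 191 genes in place of 109. DESeq2 gave 403 for that line and 783 for the let-7b/c knockout in place of 305. Limma-voom with quality weights gave 1278 for LIN28B induction (1958), 335 without vavcre, 1428 with vavcre (3634), 1056 for vavcre against no vavcre (2799) and 475 for the let-7b/c knockout. It gave the vavcre libraries a weight of 0.283 each. Only the groups compared gave 1132 for LIN28B induction, 268 without vavcre, 2007 with vavcre and 422 between the lines. The 4 LIN28B libraries as 1 group, which puts the difference between the lines into the spread, gave 169. Without the inducible let-7 and vavcre libraries the line without vavcre had 255 genes and the let-7b/c knockout 626.

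Title numbers as a replicate block gave 2185 genes for development, 3073 for the libraries labelled Lin28b knockout, 274 for LIN28B induction, 16 without vavcre, 1539 with vavcre, 435 between the lines and 35 for the let-7b/c knockout. Under this block the log2 change of Igf2bp1 in the libraries labelled Lin28b knockout turned from a fall to 0.0921 (edgeR adjusted p = 0.975). Libraries with the same number did not correlate once group means were removed (r = -0.0834 to 0.0304), so the numbers were not taken as pairs.

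Leaving out each library in turn gave 2792 to 3176 genes for development (3677), 5084 to 5421 for the libraries labelled Lin28b knockout (5941), 1095 (without wild-type bone marrow library 2) to 2672 (without vavcre library 6) for LIN28B induction and 26 (without LIN28B library 5) to 62 (without wild-type bone marrow library 2) without vavcre. It gave 2844 to 3846 with vavcre, 1376 (without LIN28B library 5) to 3152 (without vavcre library 4) between the lines and 96 (without wild-type bone marrow library 2) to 378 (without knockout library 3) for the let-7b/c knockout. A lone library left in a group was assumed to vary like the other groups. The set tests called 51 to 57 lists in place of 55. The LIN28B position difference stayed positive, at 0.1034 (without wild-type bone marrow library 2) to 0.156 (without LIN28B library 1), with exact permutation p of 0.1 or 0.0667, the smallest these sizes allow. The position differences of the let-7b/c knockout and of the libraries labelled Lin28b knockout stayed at 0.059 to 0.0918 and -0.2794 to -0.2191.

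An estimated correlation left 11 of the 55 set calls, and fry, which tests a list against no change and not against other genes, called 60 lists, 44 of the 55 among them. Position differences kept their sign and p with the 1000 genes, a prior count of 0.5 and genes at 10 CPM or more. The let-7 target median of the inducible let-7 library was -1.0929 with a prior count of 0.5 in place of -1.05, because a lower prior count widens differences of low genes. The 7-mer seed match called no comparison, with 0.0766 and adjusted p = 0.644 for LIN28B induction. Of named gene values under all alternatives, 3681 kept the side of the threshold. The call was lost in 306 in the same direction, gained in 13 and its direction reversed in 1. Of the 306, 134 came from leaving out a library, 82 from the block, 45 from only the groups compared, 24 from quality weights, 20 from the 4 libraries as 1 group and 1 from DESeq2. In depth, a gene with 0 counts in the inducible let-7 library is bounded only at 0.116 CPM.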

Other observations

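The values of this part were put together after the results above were seen, and no cause was tested. The leading 2 components of the log2 CPM values held 32.1% and 23.8% of the variance. Replicate libraries correlated at 0.941 (the vavcre pair) to 0.986 within groups.

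The counts of let-7 targets are set side by side here without a test of their differences. In wild-type fetal liver against marrow 21 rose and 4 fell, after LIN28B induction 16 rose and 1 fell, in the libraries labelled Lin28b knockout 9 rose and 18 fell, in the let-7b/c knockout 1 rose and 3 fell (the list did not pass the set test in the last 2), and in the inducible let-7 library 8 lay above and 29 below the wild-type fetal liver range. Hmga2 stood at 533 CPM in wild-type fetal liver, 74.6 after LIN28B induction, 31.9 in wild-type marrow, 25.2 in the inducible let-7 library, 22.6 in the libraries labelled Lin28b knockout and 7.80 in the let-7b/c knockout.

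In the inducible let-7 library 56 of 66 oxidative phosphorylation genes lay above the wild-type fetal liver range and 7 below, 25 of 29 erythroid genes lay below and 1 above, and 13 of 25 granulocyte genes lay above and 9 below.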
